A study of Mus musculus with 5 samples.

How the data were processed

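RNA from sorted mouse bone marrow cells was measured on 5 Affymetrix whole-genome mouse expression arrays. Per the labels, 3 arrays carry RNA from control mice with rtTA, the doxycycline-dependent transactivator used to switch on inducible transgenes, and 2 carry RNA from MSI2-inducible mice. Per the labels' protocols, cells were sorted by flow cytometry and lysed, and the RNA was amplified linearly before biotin labelling. Each sample label describes stem and progenitor cells that carry Sca1 and Kit (LSK), whereas the series text describes Kit-positive cells without Sca1 (LK). The Sca1 gate is therefore uncertain. No value below rests on it, but whether a progenitor list describes the sorted cells or other cells does. The labels used here do not say whether, or for how long, the transgene was induced. No label says that the arrays of a group came from separate mice, so p-values measure the spread between these arrays, which may be partly technical.

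The deposited values are probe set intensities on a linear scale, already normalized between arrays by the authors. RMA, the affy package and R 2.11.0 are listed in the submitters' processing notes. The step that returned RMA's log values to a linear scale is not given in the sources used here. Medians of the 5 arrays lay between 46.4 and 48.3 intensity units. The log2 of the deposited intensities was taken, with no pseudocount, and no further normalization was applied. The number of arrays limits the precision of every value below.

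Probe sets were named from the platform annotation, and symbols were updated by Entrez ID through a table of the GRCm38.p6 assembly. Of 45101 probe sets, 64 were control probe sets. In the annotation, 34958 had 1 gene symbol, 932 had several, and 9211 were unnamed here. Of those with 1 symbol, 34754 matched the gene table. Each gene was represented by its brightest probe set, and 18193 genes were tested, of which 9012 had more than 1 probe set. No genome build is named for the values, so no coordinates are given, and the gene table was used only for names and for which genes neighbour each other.

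Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, group as the only term). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 28 lists written before the data were examined. The lists held 837 members, of which 761 had a value. Members without one were not analysed here. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run as alternatives. RNA quality was the 3' minus 5' log2 signal of the control probe sets for Gapdh and beta-actin, compared by an exact permutation test over 10 splits, whose smallest two-sided p is 0.1.

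The genes named were chosen by a rule fixed before the data were examined. It took Msi2, Numb, Hes1, Ccnd1 and Myc whatever their result. It also took, in each direction, up to 10 genes past the test with arrays that did not overlap, ranked by size and filled up by the smallest p, and up to 4 members of each list. Names that are only clone or gene model identifiers were passed over. Members named beyond the rule, and 2610035D17Rik, were chosen after their values were seen.

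Before use, the gene test and camera were tested on simulated data. Values were drawn for the 18193 genes with their measured means and moderated variances, with 200 genes changed, in 20 runs. Of genes changed by 1, 2 and 4 on the log2 scale, 14.2%, 90.8% and 99.6% were called, and 5.95% of all calls were false. With moderated variances and 200 changed genes, these shares need not hold for the measured arrays. There 4 genes passed, and Hspa1a, with a difference of 4.36, did not. A list of genes shifted by 0.75 was called in 20 of 20 runs and an unshifted list in 0 runs. The simulated genes were independent, so these runs did not test camera where genes move together.

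Alternatives covered the gene value, low values, normalization, variance model, array weights, replicate number as a block, each array left out in turn, thresholds and the set test. Figures were drawn with matplotlib from the same values.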

Results

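Expression was compared between stem and progenitor cells in 2 samples from MSI2-inducible and 3 from control rtTA mice. MSI2 is an RNA-binding protein of the Musashi family, and the series title places the comparison in normal blood formation and leukaemia. Values are log2 intensities, and differences are MSI2-inducible minus control. Arrays of both groups were alike, with a mean Pearson correlation over genes of 0.983 between control arrays (range 0.979 to 0.989), 0.976 between the MSI2-inducible arrays and 0.978 between groups (0.965 to 0.986). The first principal component held 41.8% of the variance and set MSI2-inducible replicate 1 (score 56.5) apart from MSI2-inducible replicate 2 (-5.35) and from control replicates 1, 2 and 3 (-2.87, -37.3 and -11.0). The arrays did not group by genotype.

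The mouse Msi2 gene was not detectably higher in MSI2-inducible cells. Its brightest probe set averaged 11.72 ± 0.04 (SD, n = 3) in control and 11.22 ± 0.30 (SD, n = 2) in MSI2-inducible arrays, a difference of -0.51 with a limma adjusted p of 0.883. Of its 8 probe sets, 7 were lower, with differences from -0.51 to 0.05. The labels do not give the transgene's sequence, so a probe set may not read it, and these values check nothing about the labels. Among genes tied to Musashi proteins, the Notch inhibitor Numb differed by -0.04, the Notch target Hes1 by 0.44, the G1 cyclin Ccnd1 by -0.58 and Myc by 0.05, and none passed the test (limma adjusted p 0.991, 0.911, 0.870 and 0.985).

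In MSI2-inducible cells 3 genes rose and 1 fell. Mid1, a microtubule-associated ubiquitin ligase, rose from 4.64 ± 0.34 (SD, n = 3) to 10.20 ± 0.03 (SD, n = 2), a difference of 5.56 (SE 0.24), with a limma adjusted p of 0.00944. Gdpd3, a lysophospholipase D, rose by 4.37 (SE 0.29, adjusted p 0.0324), and Ifi44l, an interferon-induced gene, by 3.67 (SE 0.25, adjusted p 0.0324). The transcript 2610035D17Rik fell by 4.38 (SE 0.26, adjusted p 0.0296). A second Mid1 probe set differed by 4.80 and the third by 0.06, and the mean of the 3 by 3.47. The other Ifi44l probe sets differed by 3.57 and 0.41, the second of 2610035D17Rik by 0.14 (adjusted p 0.971), and Gdpd3 had 1 probe set. Control means of Mid1 (4.64) and Ifi44l (2.62) and the MSI2-inducible mean of 2610035D17Rik (3.29) lay under the median of all probe sets (5.57), where the size of a difference is uncertain.

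Further genes with the smallest p in each direction did not pass limma's test. Higher in both MSI2-inducible arrays were Cxcl2, a neutrophil chemokine (difference 3.20), the adhesion gene Nectin3 (3.05), the nuclear receptor Nr4a1 (2.74), the transcription factor Zbtb16 (2.59), the kynureninase gene Kynu (2.34), Phlda1 (2.31) and the transcription factor Egr2 (2.17). Their adjusted p lay between 0.128 and 0.203. Lower in both were Rab6b (-2.72), Dnah8 (-2.52), the class I-like gene H2-M3 (-2.42), the inhibitory receptor Btla (-2.28), Zfp40 (-1.88), Arhgap31 (-1.56), Ibtk (-1.53), Zfp948 (-1.47), Cd1d2 (-1.43) and Adi1 (-1.22), with adjusted p between 0.138 and 0.318. Control means of Nectin3 (2.81), Kynu (3.48), Egr2 (4.56) and Phlda1 (4.74) lay under the median of all probe sets (5.57). So did the MSI2-inducible means of Zfp948 (3.92) and Zfp40 (5.56), and the size of such differences is uncertain. Probe sets disagreed for some of the genes named here. The second Kynu probe set differed by -0.91, and the mean of both by 0.71. The second Dnah8 probe set differed by -0.14, the 3 other Arhgap31 probe sets by -0.79 to -0.06, and the 2 other Adi1 probe sets by -1.43 and -0.18. The 2 other Ibtk probe sets differed by 0.31 and 0.08, the 3 other Zfp40 probe sets by 0.22, -2.44 and -0.21, and the 5 other Nectin3 probe sets by 0.04 to 1.19.

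**Figure D1:**
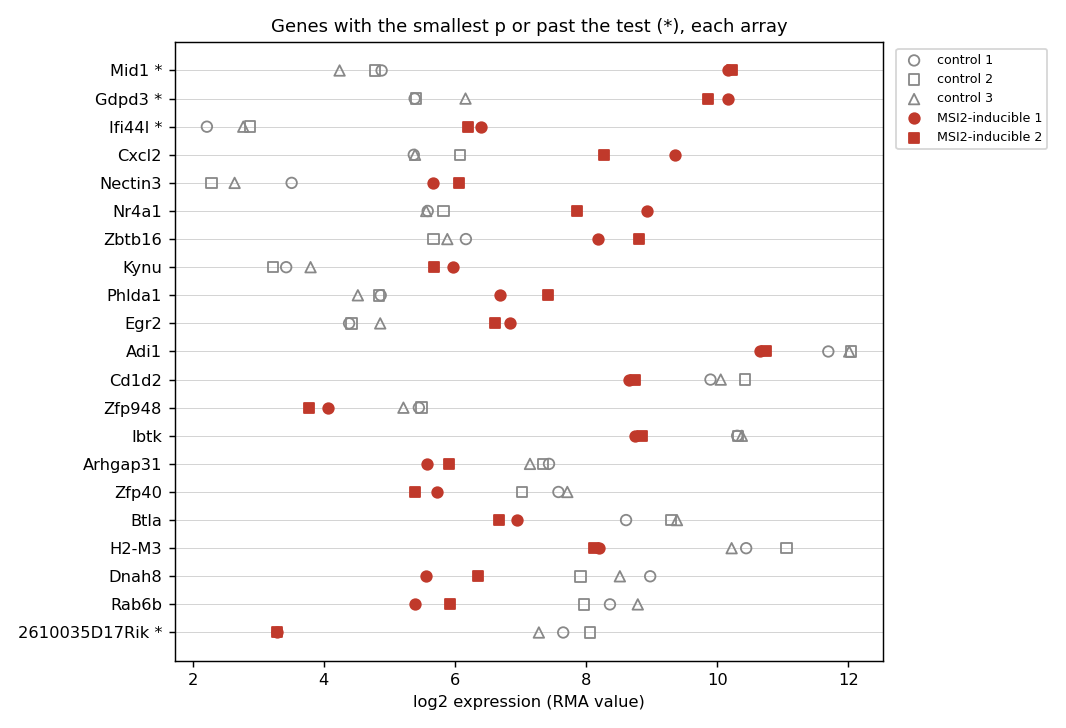
Log2 expression (x axis) of the genes with the smallest p in each direction, 1 point per array, with 3 control arrays as open grey and 2 MSI2-inducible arrays as filled red symbols and genes past the test starred. Mid1 lay at 10.17 and 10.22 in MSI2-inducible arrays and at 4.24 to 4.88 in control arrays.

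These counts are 3 higher and 1 lower of 18193 genes at a limma adjusted p of 0.05, and 4 and 3 at 0.10. An unadjusted p under 0.05 was reached by 1026 genes (5.64%, where chance gives 5%) and one under 0.001 by 46 (0.253%, chance 0.1%), and the arrays of the groups did not overlap in 18.7% of genes (chance 20%). No gene passed with any 1 of the 5 arrays left out, although Mid1 then still differed by 5.36 to 5.68. Gdpd3 and Ifi44l missed the threshold with array weights (adjusted p 0.0820 and 0.0773) and, like 2610035D17Rik, with every probe set on its own (0.110, 0.110 and 0.0866), and 2610035D17Rik differed by -2.12 (adjusted p 0.115) with the mean of its probe sets.

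Immediate early and heat shock genes, a list of stress and handling responses, were higher in MSI2-inducible cells. The median difference of 34 measured members was 0.75, and 33 were higher. Differences were 4.36 for Hspa1a and 3.85 for Hspa1b, inducible heat shock proteins, 2.74 for Nr4a1, 2.17 for Egr2 and 1.73 for Nfkbiz, an NF-kappaB regulator. Fos (0.71), Jun (0.50) and Egr3 (-0.04) differed less. Control means of Hspa1a (4.84) and Egr2 (4.56) lay under the median of all probe sets (5.57), where the size of a difference is uncertain. Of the members, 0 passed over all genes and 12 passed, all higher, adjusted over the list alone. The list's camera adjusted p was 4.84e-21, and it had an adjusted p = 0.322 with an estimated correlation. The list's median against the control mean was 0.91 and 0.64 in MSI2-inducible replicates 1 and 2 and -0.17, 0.28 and -0.18 in control replicates 1, 2 and 3. A split that set control replicates 1 and 3 against the other arrays gave this list a camera p of 8.71e-23, against 1.73e-22 for the genotypes.

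**Figure D2:**
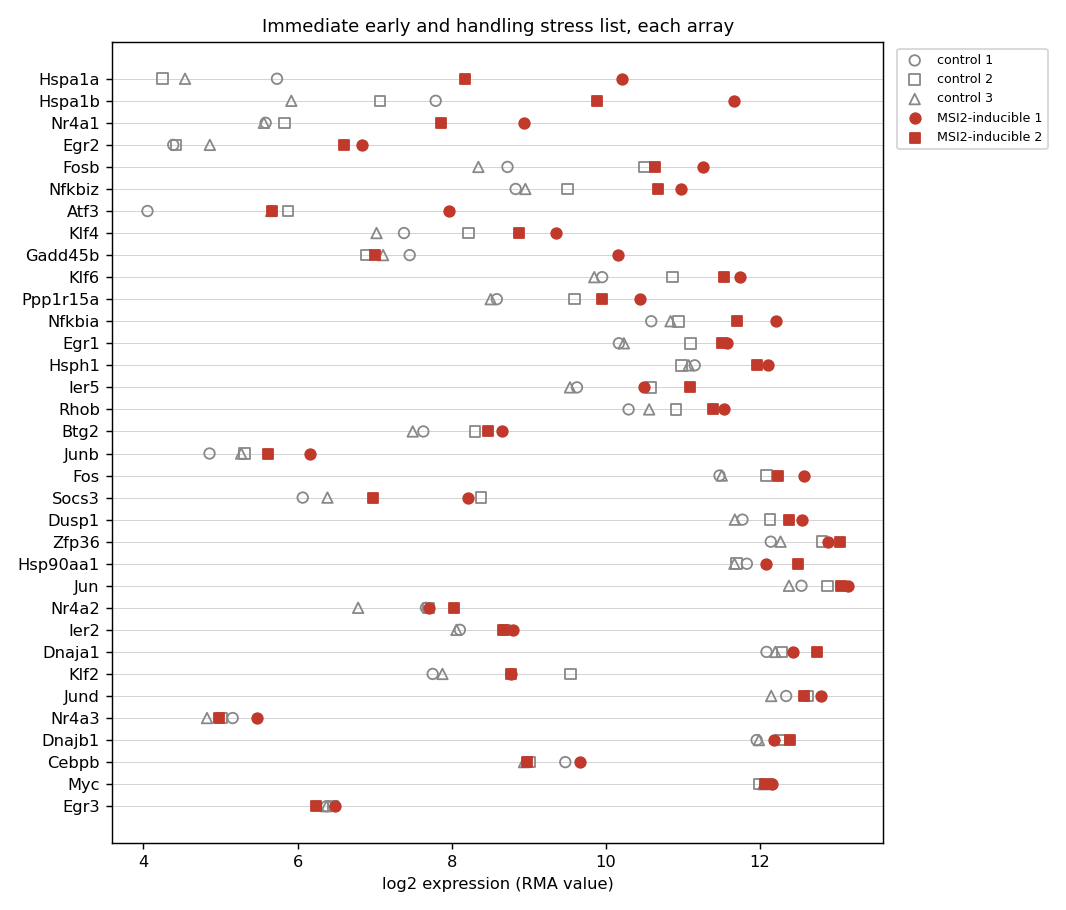
Log2 expression (x axis) of the 34 measured immediate early and handling stress genes, 1 point per array, 3 control (open grey) and 2 MSI2-inducible (filled red). Hspa1a lay at 10.21 and 8.18 in MSI2-inducible arrays and at 5.73 or below in control arrays, while control replicate 2 lay near the MSI2-inducible arrays for genes such as Fosb (10.50 against 11.25 and 10.64).

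Cholesterol synthesis genes were higher as a group, all 20 measured members with a median of 0.39. Hmgcs1, which makes the precursor of mevalonate, differed by 1.17 and was the 1 member that passed adjusted over the list alone. Insig1, a sterol sensor, differed by 0.72 and the last-step reductase Dhcr7 by 0.64. The camera adjusted p was 1.02e-06, with an adjusted p = 0.322 with an estimated correlation.

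Interferon response genes had a median difference of 0.26 over 37 members, of which 24 were higher and 13 lower. The chemokine Cxcl10 (2.34), the signalling factor Irf9 (1.05) and Oasl2 (0.94) passed adjusted over the list alone, while Ifit1 (0.04), Mx1 (0.03) and Rsad2 (-0.07) barely differed. The camera adjusted p was 0.000617, with an adjusted p = 0.322 with an estimated correlation. Without MSI2-inducible replicate 2 the camera adjusted p was 0.465.

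Ras and MAPK response genes had a median difference of 0.21 over 29 members, and Egr2, Phlda1 (2.31) and Ier3 (1.27) passed adjusted over the list alone. The camera adjusted p was 0.00142, with an adjusted p = 0.322 with an estimated correlation, and 0.460 with every probe set on its own. The list shares 3 members with the immediate early list, and without them its median was 0.12 (camera adjusted p 0.0462, chosen after the result was seen). The p53 and apoptosis list had a median of 0.19 over 28 members, with Plk2, a polo-like kinase, at 1.53 as the 1 member that passed adjusted over the list alone. Its camera adjusted p was 0.0210, with an adjusted p = 0.322 with an estimated correlation, and 0.266 without MSI2-inducible replicate 2. It was also lost with the mean of probe sets (0.0606), with every probe set on its own (0.159) and with low values left out (0.0824).

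Erythroid genes had a median difference of 0.40 over 32 members, 23 higher and 9 lower, and none passed adjusted over the list alone. The erythropoietin receptor Epor differed by 1.16, the water channel Aqp1 by 1.39 and the erythroid factor Klf1 by 1.68, whereas Gata1, the master erythroid factor, differed by -0.53. The camera adjusted p was 0.000617, with an adjusted p = 0.711 with an estimated correlation, and 0.0842 without MSI2-inducible replicate 1. The list's median was 0.60 in that array and 0.13 in MSI2-inducible replicate 2, against 0.19, -0.17 and -0.03 in control replicates 1, 2 and 3. Mature neutrophil markers moved apart in the same 2 arrays, with medians of 1.89 and -0.91, and Lcn2 lay at 11.47 and 6.94 against 7.05 to 8.95 in control arrays. The neutrophil marker S100a9 lay at 14.52 and 12.66 against 12.75 to 13.59 in control arrays, so its signal was strong in every array.

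Long-term stem cell genes had a median difference of -0.13, with 25 of 33 members lower. The list's median was -0.31 and -0.07 in MSI2-inducible replicates 1 and 2 and -0.12, 0.00 and 0.08 in control replicates 1, 2 and 3, so replicate 2 was not below every control array. Vwf, a megakaryocyte-biased stem cell gene, differed by -0.95 and the SLAM receptor Slamf1 by -1.27, while Procr differed by 0.09. Trpc6 differed by 0.64 and Ptpn21 by 0.68, but its other probe sets by -0.53 and -0.17. At an unadjusted limma p under 0.05, 2 members were higher and 3 lower, and none passed adjusted over this list alone. The camera adjusted p was 0.0434, with an adjusted p = 0.863 with an estimated correlation, and 0.744 in the other direction without MSI2-inducible replicate 1. It was also lost with low values left out (0.0928) and without control replicate 2 (0.0590) or 3 (0.445). The sex-linked list of 4 genes had a median of -1.22. Y-linked Eif2s3y differed by -2.40 (mean 5.10 against 2.70) and passed adjusted over the list alone, and Kdm5d differed by -2.09, with higher values in control replicates 1 and 3 (6.65 and 5.40) than in control replicate 2 (2.35). Xist, which marks a second X chromosome, lay between 12.49 and 12.90 in all 5 arrays. The camera adjusted p was 0.0210, with an adjusted p = 0.322 with an estimated correlation. It was 0.0548 without control replicate 3, and 0.149 and 0.137 without MSI2-inducible replicate 1 and 2.

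Of the 28 lists, 8 passed camera, 6 higher and 2 lower, 0 passed with an estimated correlation and 2 (Ras and MAPK, p53) passed fry. The same camera test called 2 to 7 lists in the 9 other splits of the 5 arrays, so the genotypes exceeded the highest other split by 1 list.

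**Figure D3:**
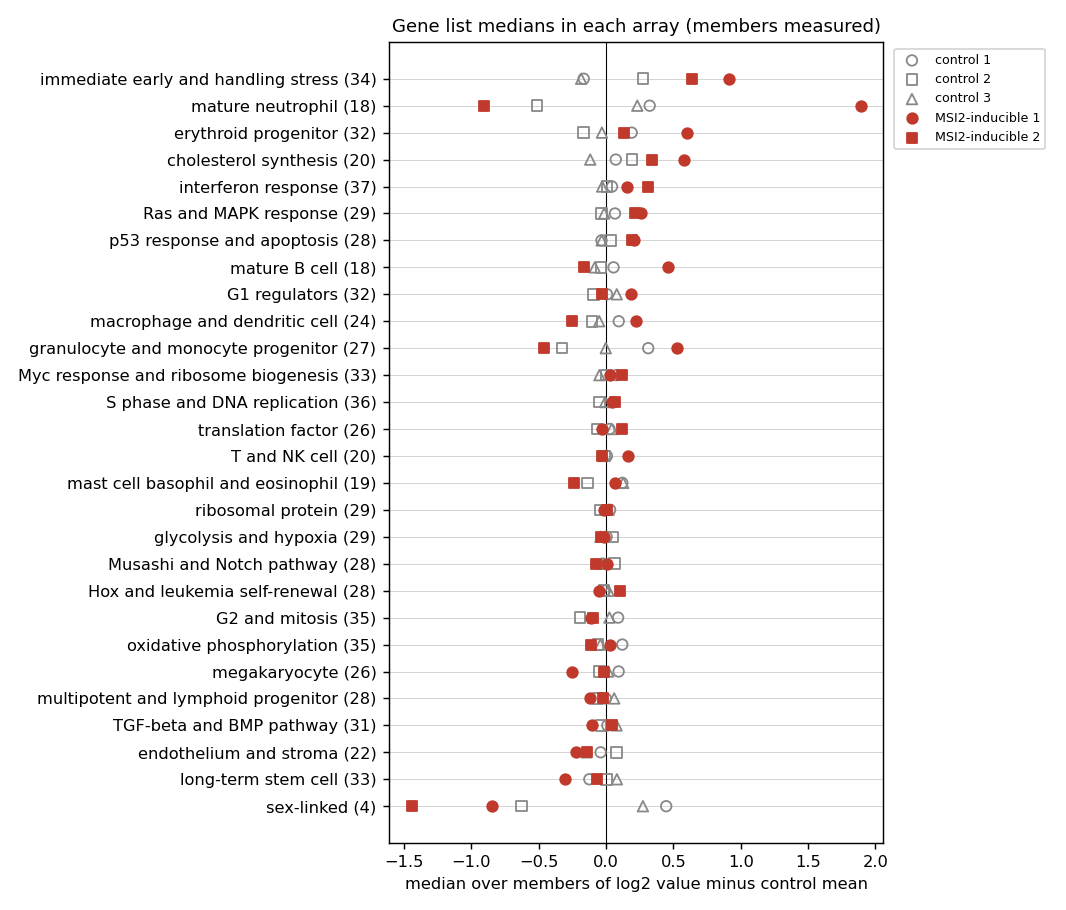
Median over each list's measured members of the log2 value minus the control mean (x axis), 1 point per array, 3 control (open grey) and 2 MSI2-inducible (filled red), with members in brackets. The 2 MSI2-inducible arrays lay apart from each other for mature neutrophil genes (1.89 and -0.91) and together for Ras and MAPK genes (0.26 and 0.22).

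The other 20 lists did not pass camera in the main setting. Mature B cell genes passed as higher with low values left out (adjusted p 0.0227). Without MSI2-inducible replicate 1, 3 of the 8 lists were lost and 4 others passed, and without replicate 2, 3 were lost and 5 others passed. Mature neutrophil genes then passed as lower (adjusted p 0.000143) without replicate 1 and as higher (6.18e-10) without replicate 2, and granulocyte and monocyte progenitor genes likewise (0.0183 and 0.00546). Myc response (0.0415) and translation factor genes (0.00996) passed as higher without replicate 1. Lists of cycling genes did not pass, with medians of 0.06 for S phase, -0.03 for mitosis and 0.10 for G1 regulators (camera adjusted p 0.659, 0.516 and 0.659). Members moved both ways. At an unadjusted limma p under 0.05, 4 G1 regulators were higher and 3 lower, and 1 mitosis gene was higher and 2 lower. Genes of the Musashi and Notch pathway had a median of -0.00 (0.659), Hox and self-renewal genes -0.01 (0.916) and TGF-beta and BMP genes -0.11 (0.811). Myc response (0.07), ribosomal protein (0.01) and translation factor genes (0.05) had adjusted p of 0.174, 0.811 and 0.318. Oxidative phosphorylation (-0.05) and glycolysis genes (0.00) had 0.441 and 0.963.

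Gapdh transcripts had a 3' minus 5' signal of 2.38 ± 0.23 (SD, n = 3) in control and 2.22 in both MSI2-inducible arrays, a difference of -0.16 (exact permutation p = 0.4). Beta-actin differed by 0.03 (exact permutation p = 0.8). Neither difference was larger than the control spread, and 0.1 is the smallest p that 3 arrays against 2 allow.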

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

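Alternatives were chosen before the data were examined, except the Ras and MAPK list without shared members and the counts of neighbouring genes, which were chosen after the result was seen. Genes higher numbered 3, and 1 with array weights, 2 with low values left out, 4 with the mean of probe sets, with trend and robust on and at an adjusted p of 0.10, and 2 probe sets, both of Mid1, with every probe set on its own; genes lower numbered 1, and 0 with every probe set on its own, 2 with low values left out, 2 with quantile normalization once more and 3 at an adjusted p of 0.10. Left-out arrays gave 0 to 0 genes in each direction (where 1 MSI2-inducible array was left, it was assumed to vary like the control arrays), and unadjusted p under 0.05 held for 1026 genes with all arrays. With replicate number as a block, 0 genes were higher and 0 lower; only 2 pairs exist and nothing in the labels pairs them (correlations of same-numbered deviations 0.134 and 0.0990). Lists past the test numbered 8, against 0 with an estimated correlation, 2 with fry and 6 to 10 with an array left out, where up to 3 of the 8 were lost and up to 5 others gained. With the block 9 passed: the long-term stem cell list was lost (adjusted p 0.229), and the mature neutrophil (higher, 0.000423) and endothelium lists (lower, 0.0231) were gained. With low values left out the mature B cell list was gained (0.0227) and the sex-linked list held 1 member, so its loss there was set by the filter. Array similarity, the lead of within-group over between-group correlation, was 0.00338, and 0.0103 with low values left out. With the mean of probe sets, differences turned direction for Ptpn21 (-0.00925), Rps6 (0.21), Paip1 (-0.32), Bmpr1a (0.11), Mecom (0.0105) and Hoxb3 (-0.48), and without _x_at probe sets for Adm (-0.18), none of them past the test. Without MSI2-inducible replicate 1, Numb (0.24; left-out arrays -0.33 to 0.24), Myc (-0.00390) and the long-term stem cell list (adjusted p 0.744; left-out arrays 0.000938 to 0.744) turned. The cause was not tested. Signal near the floor limits genes such as Ifi44l, at 2.62 in control arrays.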

Other observations

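The tests of sex, of single probe sets, of handling, RNA quality and other cell types, and of red cell RNA were chosen after the results they bear on were seen, as were the counts of neighbours in other splits and among 100 genes; the gene and list results were known when any test was written.

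Apart from the erythroid list, lists of progenitor and mature cell types did not pass camera in the main setting. Without MSI2-inducible replicate 2 mature neutrophil, granulocyte and monocyte progenitor, mature B cell (adjusted p 0.00157) and macrophage lists (0.0140) passed as higher and the megakaryocyte list (0.0310) as lower. The megakaryocyte list also passed as lower without control replicate 2 (0.0353). Medians were 0.08 for granulocyte and monocyte progenitors (adjusted p 0.659), -0.08 for megakaryocytes (0.105), -0.10 for multipotent and lymphoid progenitors (0.811), 0.18 for mature B cells (0.0856), 0.02 for T and NK cells (0.318), 0.52 for mature neutrophils (0.0856), 0.09 for macrophages and dendritic cells (0.525), 0.01 for mast cells, basophils and eosinophils (0.811) and -0.12 for endothelium and stroma (0.105). Adjusted over the list alone, Vwf (-0.95) passed among megakaryocyte genes, the chemokine Ccl5 (1.56) among T and NK genes, and the chemokine receptor Ccr2 (1.67) and the haem-degrading enzyme Hmox1 (-1.38) among macrophage genes. Prg2, the eosinophil major basic protein, lay at 9.21, 3.62 and 8.67 in control replicates 1, 2 and 3 and at 8.31 and 3.51 in MSI2-inducible replicates 1 and 2. The genotypes gave 4 genes past the test and the highest other split 0, and 8 lists against 7; in each case 1 of the 10 splits (the genotypes) gave as many, and 10 splits are too few for a share under 0.05. Without the members shared with the immediate early list, the Ras and MAPK list had a camera adjusted p of 0.0462 at the preset correlation. Phlda1 and Ier3 were still in it.

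Among the 50 genes with the smallest p, several lay next to each other in the genome. Groups wholly of opposite sex are argued against by Xist, whose difference was -0.0652 (95% interval -0.55 to 0.42). A share of male cells stays open, mainly in control replicates 1 and 3 (Eif2s3y 5.91, 3.89 and 5.49 in control against 2.76 and 2.64). By the other Eif2s3y probe set, control replicate 2 and MSI2-inducible replicate 1 both lay at 2.75. Sequence variants under single probe sets, as the cause for all of the set, are argued against by the second brightest probe set. It moved in the same direction in 80.8% of 26 genes (95% interval 60.6 to 93.4). Only direction was counted, and second probe sets moved little for genes such as Dnah8 (-0.14 against -2.52) and Arhgap31 (-0.06 against -1.56). For others, such as 2610035D17Rik, Kynu, Ibtk and Zfp40, they moved against the brightest (0.14, -0.91, 0.31 and 0.22). A further Zfp40 probe set differed by -2.44. Variants stay open for such genes. DNA segments from another strain, carried with the transgenes, may account for part: 7 pairs of neighbours lay within 10 tested genes, where matched random sets gave a median of 1 and a 95th percentile of 3 (permutation p = 0.0009). Of these, 3 came from the block of Mid1, G530011O06Rik and Erdr1, and 4 from elsewhere (such as Sik3, Cadm1 and Zbtb16). The 7 pairs formed 4 blocks. The highest count of another split was also 4, but with no block taken out, so these counts are not alike. It came from control replicate 2 set apart with control replicate 3, or with MSI2-inducible replicate 2. That count lay above the 95th percentile of the random sets as well, so the permutation p may be too small. Btla and Nectin3 moved in opposite directions, but pairs were counted whatever their direction. This test was written for the 4 genes past the test but counted on the 50, and it and the tests of sex and single probe sets were assigned to the 50 after their results were seen; of the 4, Mid1 is in a pair, and an effect of MSI2 remains open and untested.

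Immediate early and heat shock genes were higher in MSI2-inducible arrays by camera, with an adjusted p = 0.322 with an estimated correlation and 0.160 by fry, and control replicates 1 and 3 against the rest gave a smaller camera p (8.71e-23) than the genotypes (1.73e-22). RNA quality is argued against by the 3' minus 5' signal of Gapdh, which differed by -0.16 and lay within the range of the control arrays, and cells of another type in MSI2-inducible replicate 1 by the list's median of 0.64 in replicate 2, where the median of the neutrophil markers was below that of every control array. Handling before lysis could not be decided: over 34 members, the difference of control replicates 2 and 1 correlated with that between MSI2-inducible arrays and control replicate 3 at r = -0.22 (permutation p = 0.204) and rho = 0.23 across genes, and genes are not independent replicates. The criterion at first asked only for the sign of r, which went against handling; a p under 0.05 was added after the value was seen, because r had that permutation p and rho, which was not tested, had the opposite sign. Over the list, the median difference of control replicate 2 minus control replicate 1 was 0.36. Hspa1a and Hspa1b, with the largest group differences, went the other way. They lay at 4.25 and 7.07 in control replicate 2 and at 5.73 and 7.79 in control replicate 1. A single r over both kinds of gene therefore does not describe the immediate early members alone. Handling, which may differ between sorts, and an effect of MSI2 cannot be told apart here.

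Erythroid genes were higher mainly in MSI2-inducible replicate 1, with an adjusted p = 0.711 with an estimated correlation. The list's adjusted p was 0.0842 without that array, and red cell RNA in it is a candidate source: the median of 4 probe sets shared by adult globin genes lay 3.12 above the highest control array. That test was first written on probe sets of single alpha globin genes, which showed no such rise (Hba-a1 4.66 against 4.57, Hba-a2 12.13 against 12.25), and was rewritten after the shared probe sets were seen, so the probe sets disagree. Epor (8.30 and 7.89) and Aqp1 (9.23 and 8.62) lay above every control array in both MSI2-inducible arrays, so a biological difference in some members stays open and untested. The labels name a lineage gate, and whether mature red cells or RNA released from them passed it was not measured.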
